A study of Caenorhabditis elegans with 6 samples.

How the data were processed

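UNC-55::GFP binding was measured by ChIP-seq in 3 ChIP samples, each with an input sample of the same replicate number, per the labels. Worms were crosslinked with formaldehyde and chromatin was precipitated with anti-GFP antibodies, per the labels' protocols. Every sample label names UNC-55::GFP at the L2 stage, and that assignment was used, although the series title names another factor and stage. Samples were grouped as UNC-55::GFP ChIP (3 samples) and input (3 samples), with replicate numbers taken from the sample titles.

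The deposited files were 4 peak lists in GFF3 format, 1 for each ChIP replicate and 1 for the whole series. Peaks were called with PeakSeq on WormBase WS220, per the file headers and source column. The aligner, the version and thresholds of the caller, and how the replicates were pooled for the combined list are not given in the sources used here. The score column of each deposited list holds the caller's own p-value or q-value for each peak, at most 0.001 in every list, and the file headers do not say whether it is adjusted. Where neighbours in the numbering of the peaks departed from the order of these values, the departure was in all cases within the ratio of the peak numbers (relative tolerance 1e-06), as an adjusted q-value (p multiplied by the number of tests and divided by the rank) would give. The values are therefore called q here. The other columns used are start and end positions, counted from 1 with both ends included. The lists hold no read counts, so the depth per sample is unknown and no interval for enrichment can be given. Exact intervals for shares of peaks cover counting error only and treat peaks as independent. Peaks were ranked within each list by q and, where tied, by peak number.

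Peaks were compared by position only. The gene table used here is on the assembly WBcel235, which is not the build of the lists, and coordinates were not converted. Tests of distance to transcription start sites, of gene lists and of the nuclear receptor half-site were therefore not run. By the rule fixed before the data were examined, the regions named are then the 10 best-scored combined peaks present in all 3 replicates and the best-scored peak of each chromosome. Other regions named below were chosen after their values were seen.

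Peaks were called shared when they overlapped by at least 1 bp. Chance overlap came from rotating each list by its own random offset along each chromosome, 1000 times, with the end of the last peak in any list taken as the end of the chromosome (100 Mb in all). Rank concordance was Spearman's rho over matched peaks, each peak of the shorter list paired with its best match in the longer one. Chromosome densities and the share of replicate 1 peaks found in another replicate were compared between 1 Mb bins of a chromosome and those of all others by two-sided permutation tests with 100000 permutations. For the latter, bins needed at least 5 peaks of replicate 1. Benjamini-Hochberg adjustment was applied over the 3 pairs, 6 chromosomes, 12 tests or 96 tests of a family, with a threshold of 0.05. The central 50% of each chromosome was tested by rotation. Gaps between neighbours were compared with 100 random placements of peaks of the same widths on the same chromosomes. Shares have exact (Clopper-Pearson) 95% intervals. The planned comparisons were the size of the lists, their overlap and rank concordance and the X share. Those of densities, of the 100 best-scored peaks, of the chromosome IV share, of the peaks of replicate 1 found in the others, of the central 50% and of neighbouring peaks were added after the data were examined. Peaks are not independent samples, and the bin tests treat neighbouring bins as exchangeable.

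The overlap and rotation code was tested on simulated data: for 3 simulated lists of the real sizes with 1000 planted shared sites, 1000 were recovered in all 3. Rotations of these lists against the 1000 planted sites gave at most 2. Each planted site was copied to every list with a shift that left it overlapping, so its recovery checks the code only. Of 40 null comparisons between pairs of lists of 1000 peaks, 1 passed the threshold. The simulated peaks of both checks were placed at random, without the clustering of the real lists. Overlap counts had 0 differences from bedtools. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, bedtools 2.31.1 and matplotlib 3.10.9.

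The alternatives fixed before the data were examined were leaving out each replicate, a reciprocal overlap of at least 50%, midpoints within 200 bp, the better-scored 50% of each list, the same number of best-scored peaks from each list, single replicates in place of the combined list, and combined peaks found in all 3 replicates. Alternatives added later were merged replicate peaks in place of the combined list, leaving out the part of chromosome IV that is empty in the combined list or the whole of chromosome IV, bins of 2 Mb and 0.5 Mb, and distances of 1 kb and 4 kb between neighbours.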

Results

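UNC-55 is the C. elegans member of the COUP-TF family of nuclear receptors, known for its role in the ventral cord motor neurons that use GABA. Its binding to chromatin was mapped by ChIP-seq in hermaphrodites at the second larval stage, with an antibody to GFP and a strain carrying an integrated transgene on chromosome III. The transgene expresses the UNC-55a isoform fused to GFP from the ttr-39 promoter, together with a wild-type copy of dpy-20, and the labels describe expression in GABA motor neurons of the ventral cord with some ectopic expression in other cells. The series held 3 ChIP samples and 3 input samples of chromatin that had not been precipitated. Binding regions, called peaks below, were listed for each ChIP replicate and in 1 combined list, all on the WormBase WS220 genome. The inputs had no peak list of their own among the files used here. The labels do not say whether the replicates came from separate cultures, so differences between them may be technical, and the depth behind each list is unknown.

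The combined list held 8836 peaks covering 4790 kb, or 4.79% of the sequence spanned by peaks. Replicate 1 had 6805 peaks, replicate 2 had 4909 and replicate 3 had 2803, a mean of 4839 ± 2002 (SD, n = 3). The longest replicate list was thus 2.43 times the shortest, and the replicates covered 2.45 ± 1.06% of the spanned sequence (SD, n = 3). Peaks were similar in size in all lists. The median width was 425 bp in the combined list, with quartiles of 313 and 634 bp, and 412 ± 7.6 bp in the replicates (SD, n = 3). Broad regions were few: 138 combined peaks reached 2000 bp, and 127 of these overlapped a peak in all 3 replicates.

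Of the 10 combined peaks with the best caller score that were present in all 3 replicates, 7 were on X, at positions 2996211 to 2997936, 4208438 to 4210125, 6295872 to 6297311, 8035594 to 8037036, 11093538 to 11095851, 14525065 to 14527115 and 16927925 to 16932011. Among the 10 best-scored peaks of each replicate, X held 7 in replicate 1, 4 in replicate 2 and 3 in replicate 3. In replicates 2 and 3, 6 and 8 of the 10 places were taken by a region at the right end of chromosome I and by regions whose edges lay within 10 bp of one another in all 3 replicates, and in replicate 1 such sharp-edged regions took 3. The X peak from 7776511 to 7777517, of ranks 6, 4 and 4 in replicates 1, 2 and 3, is sharp-edged and is in both of these counts. The 7 combined X regions were between 1440 and 4087 bp wide and ranked 16 or better in every replicate. The X peak from 14525065 to 14527115 held rank 2 in replicate 1, rank 3 in replicate 2 and rank 8 in replicate 3. The other members of this group were the widest peaks of the combined list. One spanned 10294 bp of chromosome I, from 5371818 to 5382111, with ranks of 4, 9 and 30 in replicates 1, 2 and 3. Another spanned 7045 bp of chromosome III, from 5754221 to 5761265, with ranks of 16, 23 and 36. The third spanned 6464 bp of chromosome IV, from 11694509 to 11700972, and held ranks 1, 2 and 3. Both edges of that chromosome IV region fell within 7 bp of one another in the 3 replicates, against a median spread of 131 bp over the 2668 peaks of replicate 1 found in both other replicates. It is one of the sharp-edged regions taken up under the other observations. Whether its signal comes from extra DNA carried by the transgene stays open there.

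The caller's q value was listed as 0 for 8 of these 10 combined peaks, while the other two, on X, were listed at 5.1e-301 and 3.18e-292. The scores are the authors' and rank peaks within a list only. On chromosome II the best-scored combined peak lay at 5543202 to 5544466, with rank 15 in the combined list and ranks of 20, 22 and 21 in replicates 1, 2 and 3. On chromosome V it lay at 9729718 to 9732455, with rank 23 in the combined list and ranks of 53, 44 and 185. No gene is named for any region, because the gene table used here belongs to a different assembly.

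Replicate lists were compared to ask which regions were bound reproducibly. Of the combined peaks, 2603 (29.5%, exact 95% interval 28.5 to 30.4%) overlapped a peak in all 3 replicates by at least 1 bp. Another 2027 overlapped peaks in 2 replicates, 2052 in 1 and 2154 in none. The peaks found in all 3 were the broader ones, with a median width of 594 bp against 474 bp for those in 2 replicates, 376 bp in 1 and 262 bp in none. They were also the better-scored ones, with a median q of 2.12e-38 against 8.6e-05 for peaks found in no replicate. All of the 100 best-scored combined peaks and 974 of the best 1000 were found in all 3 replicates. Of the 2154 peaks found in none, 5 lay in the better-scored 50% of the combined list. Rotating each replicate list along the chromosomes left 1.82 ± 1.38 such peaks on average (SD over 1000 rotations) and never more than 7 (one-sided permutation p = 0.001, the smallest that 1000 rotations can give). A combined peak overlapped 98.1%, 98.9% and 99.1% of the peaks of replicates 1, 2 and 3, so this test partly restates how the combined list was made. It does not measure agreement between replicates, which the pairwise comparison below does. Replicate 3 set the count: 4551 combined peaks overlapped both replicate 1 and replicate 2 when replicate 3 was left out. Of the combined peaks, 1948 had a peak in replicates 1 and 2 and none in replicate 3, against 73 that lacked only replicate 2 and 6 that lacked only replicate 1.

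**Figure D1:**
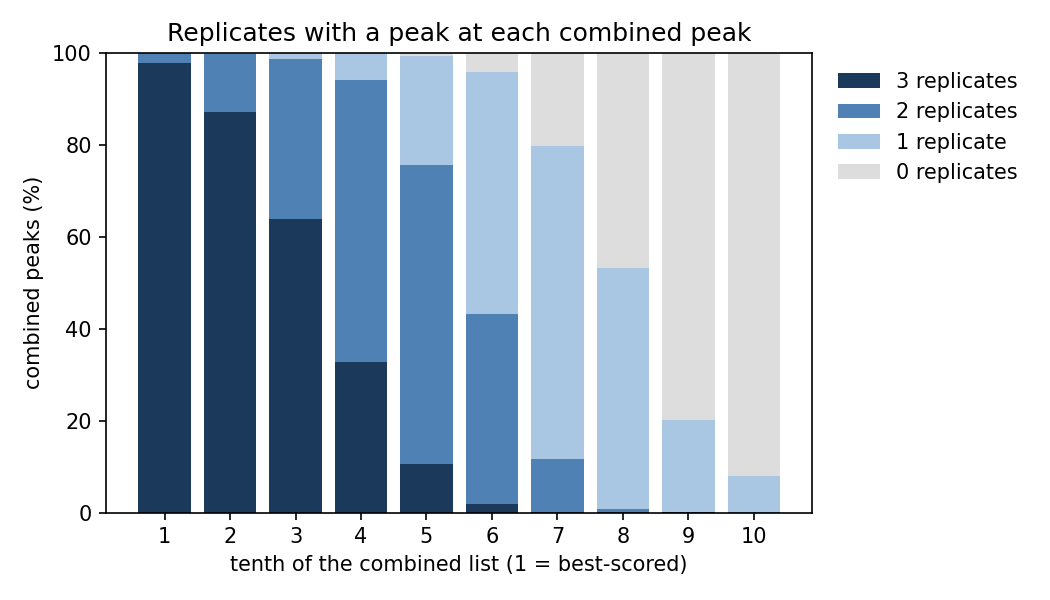
Share of combined peaks (vertical axis, percent) that overlapped a peak in 3, 2, 1 or 0 replicates, for each 10% of the combined list by caller score (horizontal axis, 1 is best-scored). All 3 replicates had a peak at 97.7% of the best-scored group, and no replicate had one at 92.1% of the worst-scored group.

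Nearly all peaks of the shorter lists overlapped a peak of the longer ones by at least 1 bp. Of the peaks of replicate 3, 99.3% overlapped a peak of replicate 1 and 96.8% a peak of replicate 2, and of the peaks of replicate 2, 96.0% overlapped a peak of replicate 1. In the other direction, 68.9% of the peaks of replicate 1 were found in replicate 2 and 40.4% in replicate 3. Rotation gave mean overlaps between 5.16% and 7.04% for these pairs, and each pair exceeded all 1000 rotations (one-sided permutation p = 0.001, the smallest possible, Benjamini-Hochberg adjusted p = 0.001 over 3 pairs). By covered bases the Jaccard index was 0.57 for replicates 1 and 2, 0.36 for replicates 1 and 3 and 0.46 for replicates 2 and 3. Peaks matched between lists were ranked alike by the caller, with Spearman's rho of 0.82 for replicates 1 and 2, 0.74 for replicates 1 and 3 and 0.75 for replicates 2 and 3. Those correlations are across peaks, which are not independent replicates, and carry no test.

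Binding regions were unevenly spread over the 6 chromosomes. Chromosome III was the densest, with 108 ± 31 combined peaks per full 1 Mb bin (SD, 13 bins) against 85 ± 28 on the other chromosomes (84 bins, two-sided permutation p = 0.00901, adjusted p = 0.018 over 6 chromosomes). Chromosome IV was sparser, at 70 ± 25 peaks per bin (17 bins) against 92 ± 28 elsewhere (permutation p = 0.00341, adjusted p = 0.018). Its bins include 1, from 10 to 11 Mb, with 0 combined peaks, and without that bin the difference was -18.3 peaks per bin (permutation p = 0.016). Chromosome V was also sparser, at 73 ± 30 (20 bins) against 92 ± 28 (permutation p = 0.00747, adjusted p = 0.018). The chromosome V difference was -14.1 peaks per bin in replicate 1 and -9.92 in replicate 2 (permutation p = 0.0193 and 0.0444, before adjustment). It was not found with replicate 3 alone, at -3.53 peaks per bin (permutation p = 0.303). These differences in peaks per bin also shrink because the replicate lists are shorter. As a share, V held 17.3% of combined peaks and 17.6%, 17.6% and 19.0% of those of replicates 1, 2 and 3. Its share of the spanned sequence was 20.9%. The densest bins were III from 8 to 9 Mb with 159 combined peaks, I from 9 to 10 Mb with 152 and II from 6 to 7 Mb with 144. Among the full bins that held any combined peak, the sparsest was V from 17 to 18 Mb with 27, against a median of 87 over all 97 full bins.

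**Figure D2:**
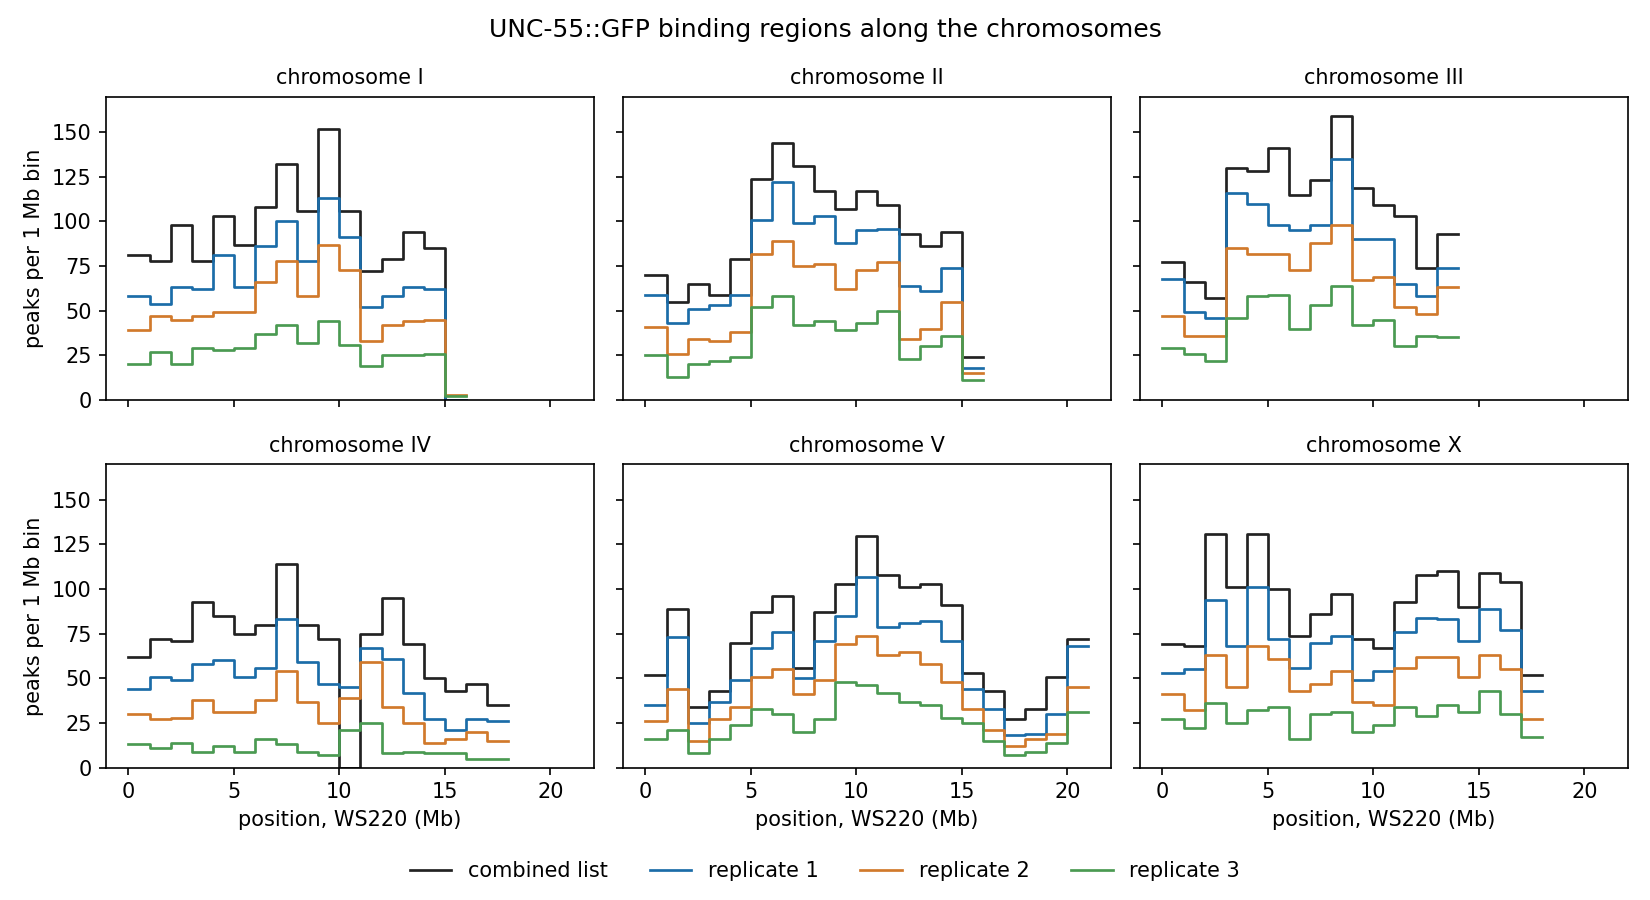
Number of peaks per 1 Mb bin (vertical axis) along each chromosome (horizontal axis, WS220 position in Mb) in the combined list and the 3 replicates; the last bin of each chromosome is incomplete. The highest bin, III from 8 to 9 Mb, held 159 combined peaks, and IV from 10 to 11 Mb held 0 combined peaks but 45, 39 and 21 peaks in replicates 1, 2 and 3.

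Over the whole lists, the X chromosome held 18.8% of combined peaks (exact 95% interval 17.999 to 19.6%) and 18.5 ± 0.1% of replicate peaks (SD, n = 3), against 17.6% of the sequence spanned by peaks. Per full 1 Mb bin its 95 ± 20 combined peaks did not differ detectably from 87 ± 31 elsewhere (permutation p = 0.319, adjusted p = 0.319). Among the 100 best-scored combined peaks, 27 were on X (exact 95% interval 18.6 to 36.8%), a comparison chosen after the values were seen. Among the best 100 of replicates 1, 2 and 3, X held 30, 29 and 30. In bins, X carried 1.53 ± 1.23 of the best 100 combined peaks per Mb against 0.84 ± 1.22 on the other chromosomes (SD over bins), which did not pass after adjustment over 96 permutation tests (6 chromosomes, the best 100, 500, 1000 and 2000 peaks, 4 lists; permutation p = 0.0401, adjusted p = 0.113). The adjusted p for the best 100 was 0.0177, 0.0762 and 0.0177 in replicates 1, 2 and 3, and X did not pass in any list for the best 500, 1000 or 2000. X thus passed in 2 of its 16 tests. In the same family chromosome III passed in 11 of 16, with more peaks than the others, and IV in 10 of 16, with fewer. None of the passes of IV was in the combined list, where its smallest adjusted p was 0.0818 in these permutation tests. Each larger cut holds the smaller ones and the lists share peaks, so the 16 tests of a chromosome are not independent. Chromosome II passed in 1. In the better-scored 50% of the combined list the X share was 16.8%, under the share of the span. Its exact 95% interval, 15.7 to 17.9%, included that share. In the best 2000 the X share was 15.2% (exact 95% interval 13.7 to 16.9%). In the best 2000 of replicates 1, 2 and 3 it was 16.7%, 16.4% and 18.4%, each with an exact 95% interval that included the share of the span.

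Chromosome IV differed between the replicates more than any other chromosome. It held 13.8% of combined peaks, and 12.8%, 11.4% and 7.21% of the peaks of replicates 1, 2 and 3, a replicate mean of 10.5 ± 2.93% (SD, n = 3). Its share was 6.92% among combined peaks found in all 3 replicates. The combined list has no peak from 10 to 11 Mb of chromosome IV, which lowers both of its shares in that list. In that stretch, 19 merged replicate regions were found in all 3 replicates. Of the 874 chromosome IV peaks of replicate 1, 23.2% (exact 95% interval 20.5 to 26.2%) were found in replicate 3, against 42.9% of the peaks on other chromosomes. Over 1 Mb bins the difference was -18.9 percentage points (24.0 ± 9.0% in 18 bins against 42.9 ± 6.5% in 84 bins, permutation p = 1e-05, the smallest that 100000 permutations can give, adjusted p = 0.00012 over 12 tests). In replicate 2 the difference was -7.24 points (permutation p = 0.00031, adjusted p = 0.00186). Chromosome III went the other way, with 47.7% of its 1192 replicate 1 peaks found in replicate 3 (+9.89 points over bins, permutation p = 0.00058, adjusted p = 0.00232) and 73.7% in replicate 2 (+6.67 points, permutation p = 0.00267, adjusted p = 0.00801). The bins it was compared with include those of chromosome IV, which lower their mean and widen the difference. No other chromosome passed the adjusted threshold of 0.05 in this family. All comparisons of this paragraph were chosen after the values were seen.

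**Figure D3:**
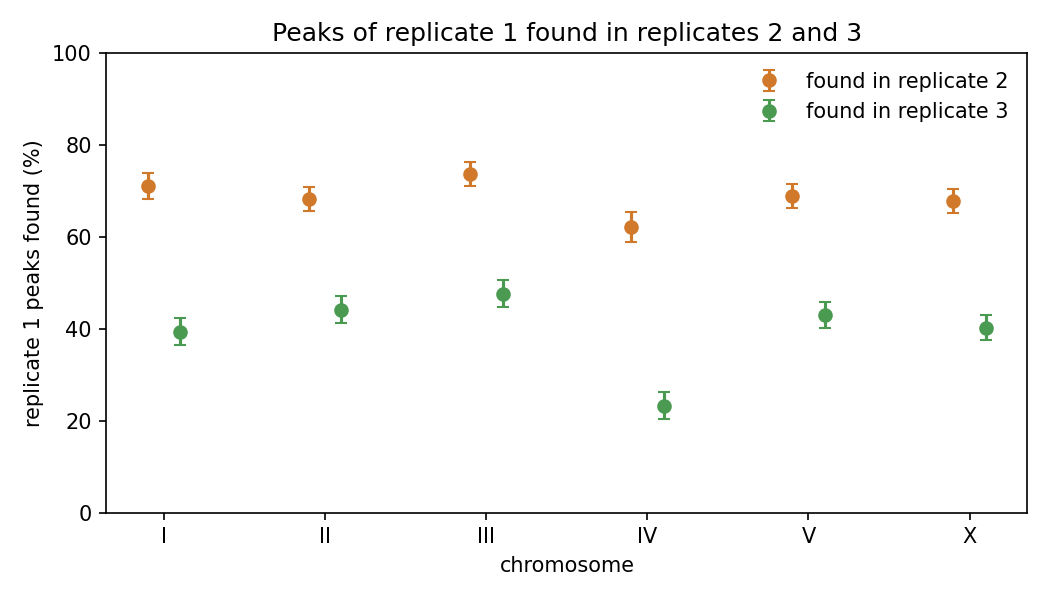
Share of replicate 1 peaks (vertical axis, percent) that overlapped a peak of replicate 2 or of replicate 3, by chromosome; bars are exact 95% binomial intervals. In replicate 3 chromosome IV lies at 23.2%, below the 39.3 to 47.7% of the other chromosomes.

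Along the autosomes, binding regions were concentrated in the central part of the chromosomes. The central 50% of the autosomal span held 59.4% of the 7174 autosomal combined peaks (exact 95% interval 58.3 to 60.6%) and 62.3 ± 0.66% of those of the replicates (SD, n = 3). Rotation of the peaks along the chromosomes gave 50.0 ± 3.2% (two-sided permutation p = 0.002). Chromosome V was the most centred, at 64.6%, but no single chromosome passed after adjustment over 6 permutation tests (smallest adjusted p = 0.102, chromosome I). On X the central 50% held 48.0% of peaks (exact 95% interval 45.6 to 50.4%, permutation p = 0.254).

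Peaks also lay closer together than random placement gave. In the combined list 32.5% of neighbouring peaks were separated by at most 2 kb, against 17.3 ± 0.38% when the same peaks were placed at random on their chromosomes (SD over 100 placements, one-sided permutation p = 0.0099, the smallest that 100 placements can give). The share was 25.6%, 19.0% and 11.7% in replicates 1, 2 and 3, against random means of 13.5%, 9.97% and 6.17%. The median gap between combined peaks was 4.55 kb, against 7.36 kb at random. Within 1 kb the share of combined neighbours was 19.8%, against 9.10 ± 0.26% at random (SD over 100 placements). Whether such close neighbours are separate binding regions was not tested. Random placement did not keep the uneven density along the chromosomes described above, so part of the excess may come from that. One long stretch of chromosome V was empty in every list: it ran from 17007405 to 17514448 in the combined list, 507 kb, and lay within gaps of 507 kb, 507 kb and 573 kb in replicates 1, 2 and 3.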

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

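The combined list and the replicate lists disagreed over 1 Mb of chromosome IV, and the tests of this disagreement were chosen after it was seen. No combined peak lay between 9998834 and 11020024, the longest gap of that list at 1021 kb, while replicates 1, 2 and 3 had 45, 39 and 21 peaks from 10 to 11 Mb, above the 3 that a count of 0 allows and including 10089647 to 10090881, of rank 5 in replicates 1 and 2 and rank 2 in replicate 3. Of the peaks there, 36 of 39 in replicate 2 (92.3%) and 20 of 21 in replicate 3 overlapped a peak of replicate 1, which argues against peaks of single replicates with no shared enrichment behind them, and the lowest number missing from the combined list's numbering was 4989, although 11 peaks of this stretch were among the best 1000 of replicate 1, which argues against lines removed after numbering. In the Mb on either side, a combined peak overlapped 114 of 114 peaks of replicate 1, 81 of 84 (96.4%) of replicate 2 and 32 of 32 of replicate 3, so the loss stopped near the Mb boundaries and 1 window left out when the combined list was called is a candidate explanation, and 19 of the 2648 merged replicate regions found in all 3 replicates lie in the stretch. The design gives no biological contrast here, so no biological explanation was tested.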

How the results depend on the processing

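The density, chromosome IV, central, neighbour and top 100 comparisons with their alternatives, and the alternatives to the mean peak number and to the rank correlation that leave out a replicate, were added after the data were seen. The X share turned from above the 17.6% of the spanned sequence to below it, at 16.8%, in the better-scored 50% of the combined list, no other alternative reversed a direction, and 78 of 91 values stayed on the same side of the threshold or within the allowed spread. Peaks found in all remaining replicates numbered between 2609 and 4551 when 1 replicate was left out, 4551 without replicate 3, and 1284 in the better-scored 50% of each list, which holds fewer peaks by construction. With merged replicate peaks as the base there were 2648, or 2629 without the empty stretch of chromosome IV. The share of the shorter list that overlapped, 97.4% on average over the 3 pairs, was 87.4% with a reciprocal overlap of at least 50%, 88.4% with midpoints within 200 bp and 81.7% with the same number of best-scored peaks from each list. The mean rho of 0.77 ranged from 0.74 to 0.82 without 1 replicate and was highest without replicate 3. For chromosome II the density difference with replicate 3 alone was 8.14 peaks per bin (permutation p = 0.032 before adjustment, against 0.225 in the combined list). For chromosome V the difference with replicate 3 alone was -3.53 and no longer passed. The density alternatives were judged and counted on p before adjustment over the chromosomes. A pass of the adjusted threshold was therefore not shown for chromosome II. The excess of X among the 100 best-scored peaks passed with replicates 1 and 3 alone, at 0.88 and 0.89 peaks per bin, and not with the combined list. The X share was 21.8% with chromosome IV left out of the total, which follows from the smaller total. The chromosome IV share was 6.92% among combined peaks found in all 3 replicates, a set with no peak in the empty stretch. It was 12.8%, 11.4% and 7.21% in replicates 1, 2 and 3. Apart from those that follow from how the alternative is built, and from the chromosome IV peaks of replicate 3, tested under the other observations, the cause was not tested. No paired analysis was possible because the inputs had no peak list of their own among the files used here. The planned tests of start sites, gene lists and the half-site, with all their alternatives, were not run for want of an annotation and genome of the same build. Depth is unknown, so whether the shorter list of replicate 3 comes from fewer reads cannot be read from these data.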

Other observations

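Replicates 2 and 3 shared one best-scored region that the combined list and replicate 1 lacked, at the right end of chromosome I, the end that carries the ribosomal DNA repeats. It ran from 15064006 to 15067642 in replicate 2 and from 15064003 to 15067623 in replicate 3 and held rank 1 in both, with q listed as 0. The incomplete last bin of chromosome I, from 15 Mb, held 0 peaks in the combined list and in replicate 1, and 3 and 2 peaks in replicates 2 and 3. The regions and tests of this part were chosen after their values were seen.

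Chromosome IV was short of peaks in replicate 3. At matched rank, in each 10% of replicate 1's ranking, its peaks were found in replicate 3 at 0.55 of the number given by the other chromosomes, against 0.93 to 1.12 for those chromosomes, so weaker peaks falling under the threshold first does not account for it. In the better-scored 50% of replicate 1, 18 of 18 bins of chromosome IV lay below the other bins' median of 75.8% found, at 28.1 to 66.7%, which is consistent with a shift of caller scores along the whole chromosome. Over all peaks it was 17 of 18 bins, the exception being 10 to 11 Mb at 44.4% against a median of 42.3%. A difference of the worms or of their chromatin along chromosome IV would look the same, and no biological explanation was tested.

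A small group of strong regions had nearly fixed edges. Among the best-scored 5% of replicate 1, 8 regions found in all 3 replicates had start and end positions within 10 bp of each other, against a median spread of 245 bp for the other 332. Of these, 4 lay within 4.63 kb of chromosome I, between 7898871 and 7903499, and the others at 11027522 to 11028294 on II, 10089647 to 10090881 and 11694511 to 11700967 on IV, and 7776511 to 7777517 on X. Over the same shared peaks, 6 of the 7 present in the combined list ranked at least 5 times worse there than in any replicate, which, with regions under 10 kb apart counted once, was 3 of 4 loci against 0 of 303 other loci of that best-scored 5% (Fisher's exact p = 8.38e-07) and argues against binding of the same kind as at other shared peaks. Extra DNA copies carried by the transgene, whose parts include unc-55 from chromosome I, dpy-20 from chromosome IV and the ttr-39 promoter, may give such edges. No sharp-edged region, including those on II and X, was matched to these parts, because no gene table of this build was used. Such copies would also be present in the inputs, which had no peak list of their own. Of 5 loci, 3 ranked better in replicate 3 than in both others, against 31.3% of 307 other loci (Fisher's exact p = 0.331). The region from 11694511 on IV had q listed as 0 in every replicate, so peak number set its rank. In replicate 3, q was also listed as 0 for the regions from 10089647 on IV and 7776511 on X, so peak number set their ranks there. All sharp-edged regions except that from 11694511 on IV had a smaller q in replicate 3 than in replicate 1 (7898871 to 7899873 on I: 5.85e-187 against 1.23e-106). The X regions among the 10 best combined peaks went the other way (2996211 to 2997936: 1.87e-116 against 3.51e-264). Scores rank peaks within a list only, so with so few loci this stays open.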
